A study of Arabidopsis thaliana with 18 samples.

How the data were processed

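RNA from leaves of 5-week-old Arabidopsis thaliana plants was measured on 18 Affymetrix ATH1 arrays. The plants were wild-type Col-0, a line called 35S:AFB1 and a line called 35S:miR393, where 35S is a viral promoter used for strong expression, AFB1 is an auxin receptor and miR393 is a microRNA that lowers auxin receptor transcripts. They were grown at 20 °C with 8 h of light and 16 h of dark. Leaves were infiltrated by syringe with water or with the bacterium Pseudomonas syringae pv. tomato DC3000 (Pst) at 1000000 cfu per ml. The labels describe Trizol extraction, DNase treatment, column purification and biotin labelling of total RNA.

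The deposited values are on the log2 scale, 1 per probe set and array, and per the labels they come from RMA, a method that corrects background, makes arrays comparable and summarises the probes of each set. The software, its version, and whether all arrays were processed together are not given in the sources used here. The values of the 22810 probe sets were used as they stand. Array medians lay between 6.62 and 6.75, values between 3.17 and 15.1, and the lowest correlation of an array with another of its group was 0.981. A group mean under 6, a level chosen after the data were seen, is read as near background, and the size of a change against it is not exact. No pair of arrays had identical values and no column belonged to another sample (0 in both checks). The 64 control probe sets of the manufacturer were left out of the tests, which leaves 22746.

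Genes were named from the annotation tables supplied with the data. Of the tested probe sets, 13513 name 1 gene, 503 name several and 8730 are not listed, so they carry no gene name here. The single-gene probe sets cover 13356 genes, and 13436 of them could be placed on a locus of the TAIR10.1 annotation, which was used only for names and for the order of genes along chromosomes.

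The 6 groups of 3 arrays were compared with limma 3.58.1 in R 4.3.3, in one fit of the 6 group means over all 18 arrays, with 12 residual and 3.20 prior degrees of freedom. There were 11 contrasts: infection (Pst minus water) in each of the 3 lines, each transgenic line minus Col-0 in water and in Pst, 35S:miR393 minus 35S:AFB1 in water and in Pst, and the interactions, which are the infection effect in a transgenic line minus that in Col-0. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets of a contrast, and every adjusted p for a probe set is limma's, two-sided. The labels do not say whether replicates came from separate plants or separate inoculations, so the p-values measure only the spread between these samples, which may be technical. With 3 arrays a group, the number of arrays limits the precision, and the median standard error was 0.16 on the log2 scale for a difference between groups and 0.22 for an interaction. The titles of the water arrays say 0 h and those of the Pst arrays 24 h, while the design gives a harvest 24 h after inoculation. The values do not settle which is right, so a time difference between water and Pst leaves cannot be separated from infection.

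There were 25 gene lists of pathways, hormones, defence, cell types and reference genes, with 425 genes. Few of them are named by the annotation used here: 58 genes in 19 lists. A list gene is called measured here when the annotation names a probe set of its own for it. Other members may lie on the array without a name. A list was tested when at least 2 of its genes were measured, which held for 13 lists, using for each gene the probe set with the highest mean. The test was camera from limma with its preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. It was repeated with a correlation estimated from the data and with fry, which tests whether a set's genes move on balance one way and does not compare the set with other genes. Member counts are given over all probe sets and adjusted over the list alone. The groups, contrasts, test, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names 20 fixed genes, of which 1 (GH3.3) has a name in the annotation used here. It adds, per comparison, the 6 most risen and 6 most fallen called single-gene probe sets whose groups do not overlap, and per list up to 4 called members with the largest change, or else the member with the smallest p. It gave 72 genes, and genes named outside it are said to be so.

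The test was checked on simulated data with 22746 probe sets, in which 200 were shifted by 0.5, 1 or 2 on the log2 scale. In the infection contrast it recovered 23.9%, 85.1% and 98.5% of them by size, with 5 false calls. In the contrast of lines in Pst it recovered 26.9%, 83.6% and 100%, with 7 false calls. For the interaction it recovered 1.49%, 52.2% and 95.5%, with 3 false calls. Among 40 simulated lists camera called 10 of 10 shifted lists and 1 other. The simulated genes varied independently of each other, so this check cannot decide whether the preset inter-gene correlation suits the real lists.

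Whether replicate numbers pair arrays across groups was checked by correlating residuals. They pair groups here where all arrays with the same number correlated above 0.1. This held for 5 of 15 pairs of groups (correlations of 0.12 to 0.68, against -0.20 to 0.41 in the other pairs), namely Col-0 with 35S:miR393 in water, all pairs of lines in Pst, and Col-0 in Pst with 35S:AFB1 in water. A water group and a Pst group of the same line were not paired in this sense. The alternatives tried were array median centring, quantile normalization, leaving out the dimmer probe sets, trend with robust eBayes, array weights, the replicate number as a block, a fit of only the compared groups, an adjusted p under 0.01, a log2 change of at least 1, and leaving out each array in turn. A block within treatment, the 5′ minus 3′ gap of the spike-in controls as a covariate, and families of genes by symbol were added after seeing the data. Other splits of the arrays were refitted, all 10 for each comparison of 3 with 3 arrays and 100 drawn splits for each interaction. For the transgenic lines set side by side, unchanged lines were simulated against the same Col-0 arrays, and 100 draws of arrays were made. Simulations and fits used statmod 1.5.0 beside limma, and figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.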

Results

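The data are expression profiles of Arabidopsis leaves from 3 plant lines, each infiltrated with water or with Pst DC3000, with 3 arrays in each of the 6 groups. The question named by the series is how auxin signalling affects the response to this bacterium. The lines were wild-type Col-0, 35S:AFB1 and 35S:miR393. The strongest axis of variation, the first principal component, took 78.9% of the variance and separated every Pst array from every water array, and the second took 4.64%. Of the 20 genes fixed by name, 19, among them the auxin receptor genes, were not analysed here by name, so the levels of the receptors themselves are not reported.

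Infection of Col-0 leaves changed a large share of the transcriptome. The gene of the coumarin enzyme feruloyl-CoA 6'-hydroxylase (AT3G13610) rose 112-fold, from a mean log2 value of 6.14 ± 0.61 (SD, n = 3) in water to 12.94 ± 0.47 in Pst. UGT76B1, whose product glucosylates the immune regulators salicylic acid and isoleucic acid, rose 44.4-fold. BSMT1, whose enzyme makes methyl salicylate, rose from 5.12 ± 0.25 to 11.64 ± 1.17 (SD, n = 3), and GH3.3, which encodes an enzyme that conjugates auxin to amino acids, from 5.15 ± 1.01 to 9.39 ± 0.48, both from a water mean under 6, near background. In the other direction, DRT100, which encodes a leucine-rich repeat protein, fell from 10.91 ± 0.34 to 5.96 ± 1.17 (SD, n = 3), a Pst mean near background, so the size of its fall is not exact.

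Across all probe sets, limma called 9590 of 22746 (42.2%), of which 4794 were higher and 4796 lower in Pst than in water, and 4604 changed by at least 1 on the log2 scale. The groups did not overlap for 11124 probe sets (48.9%), where chance gives 10%. Among the genes that rose most in Col-0, AT3G13610 changed by 6.80 on the log2 scale (SE 0.61, adjusted p = 1.04e-06), BSMT1 by 6.52 (SE 0.52, adjusted p = 4.37e-07) and UGT76B1 by 5.47 (SE 0.53, adjusted p = 1.76e-06). AT3G57950 rose by 5.40, the AAA-type ATPase gene AT3G28510 by 5.05, and AT1G43910, which also encodes an AAA-type ATPase, by 4.72. Those that fell most among single-gene probe sets were DRT100 (-4.95, SE 0.49, adjusted p = 2.14e-06), AT2G10940 (-4.85), the GDSL lipase gene AT1G29660 (-4.79), the aspartyl protease gene AT1G09750 (-4.50), the endoglucanase gene GH9C2 (-4.45) and the pectate lyase gene AT1G67750 (-4.36).

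Of the auxin lists in infected Col-0, GH3 moved most. 3 of its 4 measured members rose, also when adjusted over the list alone, namely GH3.3 (4.24, SE 0.47, adjusted p = 5.29e-06), WES1 (2.47-fold) and GH3.17 (0.77, SE 0.24). The GH3.17 call was lost without Col-0 water replicate 2 (0.74), Pst replicate 2 (0.62) or Pst replicate 3 (0.68), and with the spike-in gap as covariate (0.76). The GH3 list as a set had a median change of 1.04 and a camera adjusted p of 0.0393, but an adjusted p = 0.23 with an estimated correlation. Without Col-0 water replicate 2 the camera adjusted p was 0.0574, without Pst replicate 2 it was 0.0516, with the replicate block 0.0525 and without the dimmer probe sets 0.117. Of 4 measured genes of auxin synthesis, conjugates and transport, AT1G14130, which encodes an auxin oxidase, rose by 1.82 and the others did not pass. That list's median was -0.23 while its mean was 0.26 and the test pointed up (adjusted p = 0.992). Of 5 measured Aux/IAA repressor genes, IAA29 fell (-0.66, SE 0.15, adjusted p = 0.00187) and 4 did not pass (list adjusted p = 0.769). The means of GH3.17 and IAA29 lay under 6, near background, in both groups, so the sizes of their changes are not exact.

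Most measured genes of salicylic acid defence (2 of 28 list genes measured) and of pattern-triggered immunity (4 of 22) rose in infected Col-0. Both measured salicylic acid defence genes rose, GRX480, which encodes a glutaredoxin that binds TGA transcription factors, by 3.45 (SE 0.54) and SAG101, whose protein partners EDS1, by 1.99 (SE 0.26). The list had a median of 2.72 and a camera adjusted p of 0.0376, or an adjusted p = 0.23 with an estimated correlation. Of 4 pattern-triggered immunity genes, the transcription factor gene WRKY53 (2.13), the receptor-associated kinase gene BIK1 (1.67) and the receptor gene EFR (0.87) rose and 1 did not pass. That list had a median of 1.27 and a camera adjusted p of 0.0376, with an adjusted p = 0.23 with an estimated correlation. Without the dimmer probe sets neither list passed (adjusted p of 0.115 for salicylic acid and 0.153 for immunity). Of 4 jasmonate response genes BSMT1 and JMT, which encodes the jasmonate methyltransferase, rose (6.52 and 2.40), and 2 did not pass, among them the defensin gene PDF1.2 (0.50). As a set the jasmonate response list did not pass (adjusted p = 0.0754). Single measured members of other lists that rose were OPCL1 of jasmonate synthesis (1.53), EIN3, the transcription factor of ethylene signalling (1.62), AT2G04400 of tryptophan synthesis (2.02) and UGT74B1 of indole glucosinolates (0.74). The UGT74B1 call was lost without Col-0 water replicate 3 (0.59) or Pst replicate 2 (0.55), and with the spike-in gap as covariate (0.68).

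The measured photosynthesis genes (10 of 52 in the list) fell together in infected Col-0. All 10 measured members were lower, also when adjusted over the list alone, with SBPASE (-1.74, SE 0.29) and PRK (-1.15, SE 0.22), both of the Calvin cycle, LHCB4.2 of the light-harvesting antenna (-0.97, SE 0.25) and ATPC1 of the chloroplast ATP synthase (-0.92, SE 0.21) changing most. The LHCB4.2 call was lost with only the compared groups (-0.97) and with the spike-in gap as covariate (-0.78). The list had a median of -0.68 and a camera adjusted p of 0.00668, but an adjusted p = 0.38 with an estimated correlation. Of 4 aliphatic glucosinolate genes, 3 fell, namely GSTU20 (-2.91, SE 0.54), BCAT4 (-2.65, SE 0.64) and AT2G31790 (-2.33, SE 0.28), and 1 did not pass. The median of that list was -2.49 (adjusted p = 0.0584).

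The remaining lists in infected Col-0 did not pass as sets. Of 2 senescence genes the transcription factor gene WRKY6 rose (2.49) and SAG29 did not pass (0.97, list adjusted p = 0.0584). Of 3 sugar transport genes SWEET4 rose (2.96), SWEET11 fell (-0.90, a call lost at -0.67 with the spike-in gap as covariate) and 1 did not pass, and the median of that list was -0.09 while its mean was 0.65 (adjusted p = 0.693). Of 2 abscisic acid genes COR15A fell (-2.12) and the other did not pass (list adjusted p = 0.656). Among 4 guard cell markers AT1G22690, a gene of the gibberellin-regulated family, fell (-3.38) and 3 did not pass (list adjusted p = 0.584). The clock gene GI fell (-0.69), a call lost without Col-0 water replicate 2 (-0.50), Pst replicate 2 (-0.65) or Pst replicate 3 (-0.50), with the spike-in gap as covariate (-0.51) and with only the compared groups (-0.69). DFR, the one measured phenylpropanoid and flavonoid gene, did not pass (-0.13). Of 4 reference genes AT4G34270 rose (0.54) and GAPC2 fell (-0.45), the latter not called without Pst replicate 2 (-0.30), with quantile normalization (-0.30), with only the compared groups (-0.45) or with the spike-in gap as covariate (-0.36), while the list did not move as a set (adjusted p = 0.992). The lists of auxin receptors, SAUR genes, camalexin, vascular, epidermis and dividing cell markers had 0 named members and were not analysed here.

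**Figure D1:**
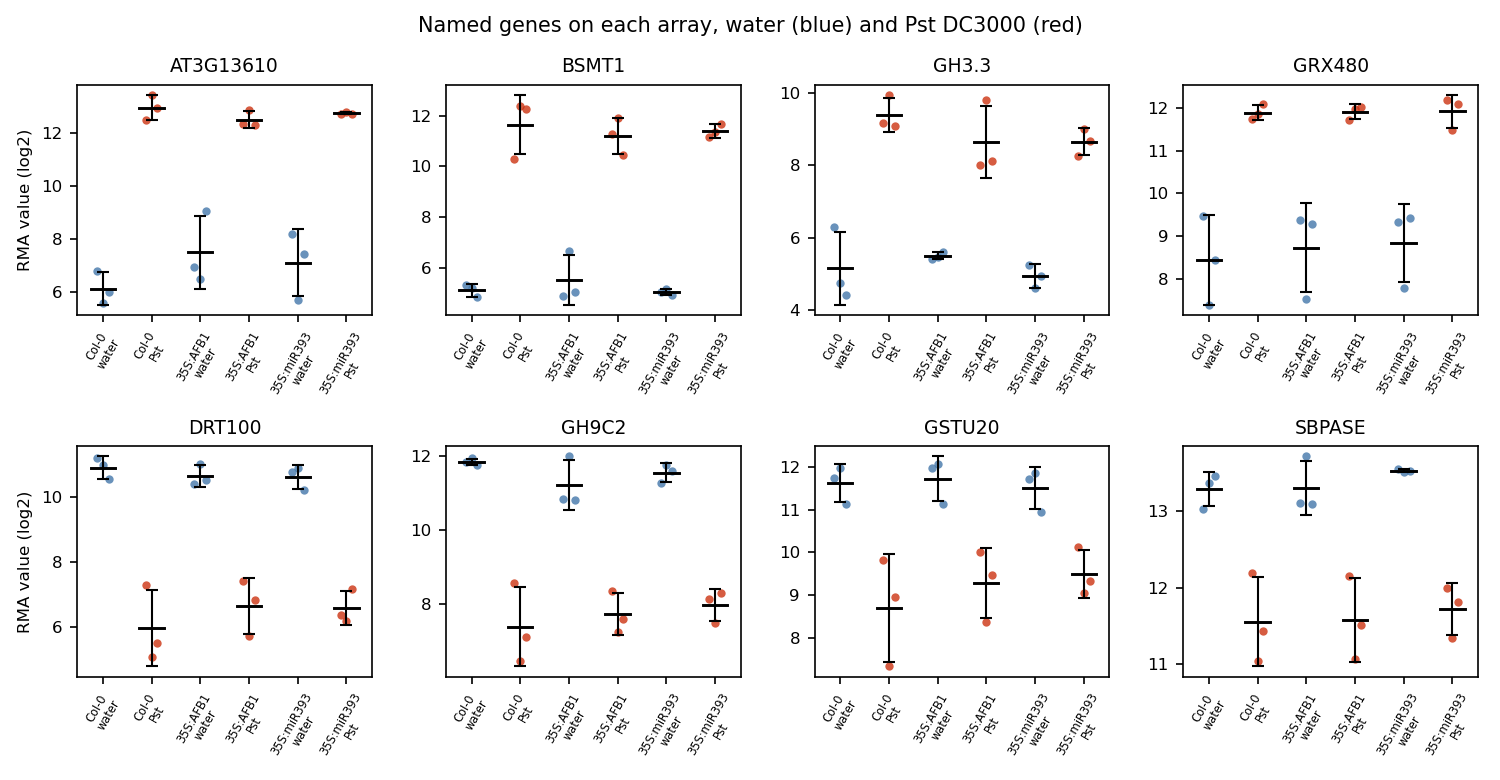
Log2 expression of 8 named genes on each array (points), with the mean of each group as a bar mark and its SD (n = 3), water in blue and Pst in red, for the 3 plant lines. AT3G13610, BSMT1, GH3.3 and GRX480 were higher and DRT100, GH9C2, GSTU20 and SBPASE lower in Pst in every line.

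Infection of 35S:AFB1 leaves moved leading genes of the Col-0 response. AT3G13610 rose by 4.98 on the log2 scale, BSMT1 by 5.67, UGT76B1 by 4.40 and GH3.3 by 3.14 (adjusted p = 0.000116). Among the fallen were DRT100 (-3.99), AT2G27420, which encodes a papain-like protease (-4.32), and AT2G10940 (-4.26). Photosynthesis and glucosinolate genes were among the fallen and defence genes among the risen. limma called 7950 probe sets (35.0%), 3872 higher and 4078 lower, and 3600 changed by at least 1. Groups did not overlap for 10078 probe sets (44.3%), where chance gives 10%.

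By list in 35S:AFB1, 2 of 4 GH3 genes rose over all probe sets (GH3.3 and WES1, 1.07) and 3 when adjusted over the list alone, with a list median of 0.85. The camera adjusted p for GH3 was 0.0337 and the adjusted p = 0.304 with an estimated correlation. Without 35S:AFB1 water replicate 3 the GH3 camera adjusted p was 0.0803, and without Pst replicate 2 it was 0.0700. Both salicylic acid genes rose (GRX480 3.18, SAG101 1.75), as did 3 of 4 pattern-triggered immunity genes (WRKY53 1.66, BIK1 1.48, EFR 0.85), each list with a camera adjusted p of 0.0306 and an adjusted p = 0.304 with an estimated correlation. The WRKY53 call was lost without 35S:AFB1 water replicate 2 (1.18) or Pst replicate 3 (1.41), and the immunity list had an adjusted p of 0.0550 without Pst replicate 3. Without the dimmer probe sets the adjusted p was 0.117 for GH3, 0.0721 for salicylic acid and 0.141 for immunity. Of 10 photosynthesis genes 5 fell over all probe sets and 7 when adjusted over the list alone (SBPASE -1.72, PRK -0.99, ATPC1 -0.83), with a list median of -0.60 and a camera adjusted p of 0.00877, or an adjusted p = 0.348 with an estimated correlation. Of 4 aliphatic glucosinolate genes 3 fell (GSTU20 -2.44, BCAT4 -2.19, AT2G31790 -2.09, list adjusted p = 0.0786), and the BCAT4 call was lost without 35S:AFB1 water replicate 1 (-1.88) or Pst replicate 2 (-1.53). BSMT1 and JMT (2.51) rose in the jasmonate response list (adjusted p = 0.146), and when adjusted over the list alone its thionin gene THI2.1 fell (-0.26). WRKY6 (2.00), SWEET4 (2.63), EIN3 (1.09), OPCL1 (1.48), AT2G04400 (1.77) and AT1G14130 (1.52) rose, while COR15A (-2.10), AT1G22690 (-2.36), SWEET11 (-0.73) and GI (-0.64) fell. The SWEET11 call was lost without 35S:AFB1 water replicate 3 (-0.49), Pst replicate 1 (-0.65) or Pst replicate 2 (-0.73). The GI call was lost without water replicate 1, Pst replicate 1 (-0.61) or Pst replicate 2 (-0.57), and with array median centring (-0.58).

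Infection of 35S:miR393 leaves also raised coumarin, methyl salicylate and auxin conjugation genes. AT3G13610 rose by 5.61 on the log2 scale, BSMT1 by 6.34, UGT76B1 by 4.78 and GH3.3 by 3.71 (adjusted p = 2.6e-05). Among the fallen were DRT100 (-4.04), AT1G13650 (-3.99) and AT1G60590, which encodes a pectin lyase-like protein (-3.88). SUFE2, whose product activates the first step of iron-sulphur cluster assembly, rose by 4.52. limma called 8390 probe sets (36.9%), 4055 higher and 4335 lower, and 3943 changed by at least 1. Groups did not overlap for 11374 probe sets (50.0%), where chance gives 10%.

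By list in 35S:miR393, 3 of 4 GH3 genes (GH3.3, WES1 1.31, GH3.17 0.99), both salicylic acid genes (GRX480 3.07, SAG101 1.71), 2 of 4 jasmonate response genes (BSMT1, JMT 2.02) and 3 of 4 pattern-triggered immunity genes (WRKY53 1.67, BIK1 1.61, EFR 0.54) rose, also when adjusted over the list alone. Each of these 4 lists had a camera adjusted p of 0.0301 and an adjusted p = 0.285 with an estimated correlation. Without 35S:miR393 water replicate 1 the camera adjusted p was 0.0654 for the immunity list and 0.0517 for each of the others. Without the dimmer probe sets it was 0.0998 for GH3 and for salicylic acid, 0.134 for immunity and 0.0540 for jasmonate response and for photosynthesis. The WRKY53 call was lost without water replicate 2 (1.29) or Pst replicate 1 (1.42), and the EFR call without water replicate 2 (0.47), Pst replicate 2 (0.49) or Pst replicate 3 (0.55). Of 10 photosynthesis genes 6 fell (SBPASE -1.81, PRK -1.09, ATPC1 -0.89), with a list median of -0.62 and a camera adjusted p of 0.0117, or an adjusted p = 0.396 with an estimated correlation. Of 4 aliphatic glucosinolate genes GSTU20 (-2.01) and AT2G31790 (-1.82) fell, and 3 fell when adjusted over the list alone (list adjusted p = 0.153). WRKY6 (2.08), SWEET4 (3.32), EIN3 (0.89), OPCL1 (1.53), AT2G04400 (1.83) and AT1G14130 (1.33) rose, as did the reference gene AT4G34270 (0.46), while COR15A (-2.48), AT1G22690 (-2.45), GI (-0.66) and the auxin synthesis gene YUC6 (-0.39) fell. The AT4G34270 call was lost without 35S:miR393 water replicate 2 (0.41), and the GI call without water replicate 1 (-0.63) or 2 (-0.63) or Pst replicate 1 (-0.58) or 3. The YUC6 call was lost without any of the water replicates 1, 2 and 3, without Pst replicate 1 (-0.40) or 2 (-0.32), with array median centring (-0.34), with quantile normalization (-0.35) and with trend and robust eBayes.

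Set against each other, the infection responses of the 3 lines shared most of their calls. Between Col-0 and 35S:AFB1, 3614 probe sets rose and 3632 fell in both, where independent lists would share 816 and 860. Between Col-0 and 35S:miR393, 3673 rose and 3685 fell in both, where independent lists would share 855 and 914, and 1 probe set was called in opposite directions. In all 3 lines 3334 rose and 3392 fell, where independent lists would share 145 and 164. Across probe sets, which are not independent replicates, the log2 changes correlated with those of Col-0 at r = 0.969 for 35S:AFB1 and 0.961 for 35S:miR393. Changes were smaller than in Col-0 for 5627 of 7246 probe sets called in both Col-0 and 35S:AFB1 (77.7%), and for 5055 of 7359 called in both Col-0 and 35S:miR393 (68.7%).

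**Figure D2:**
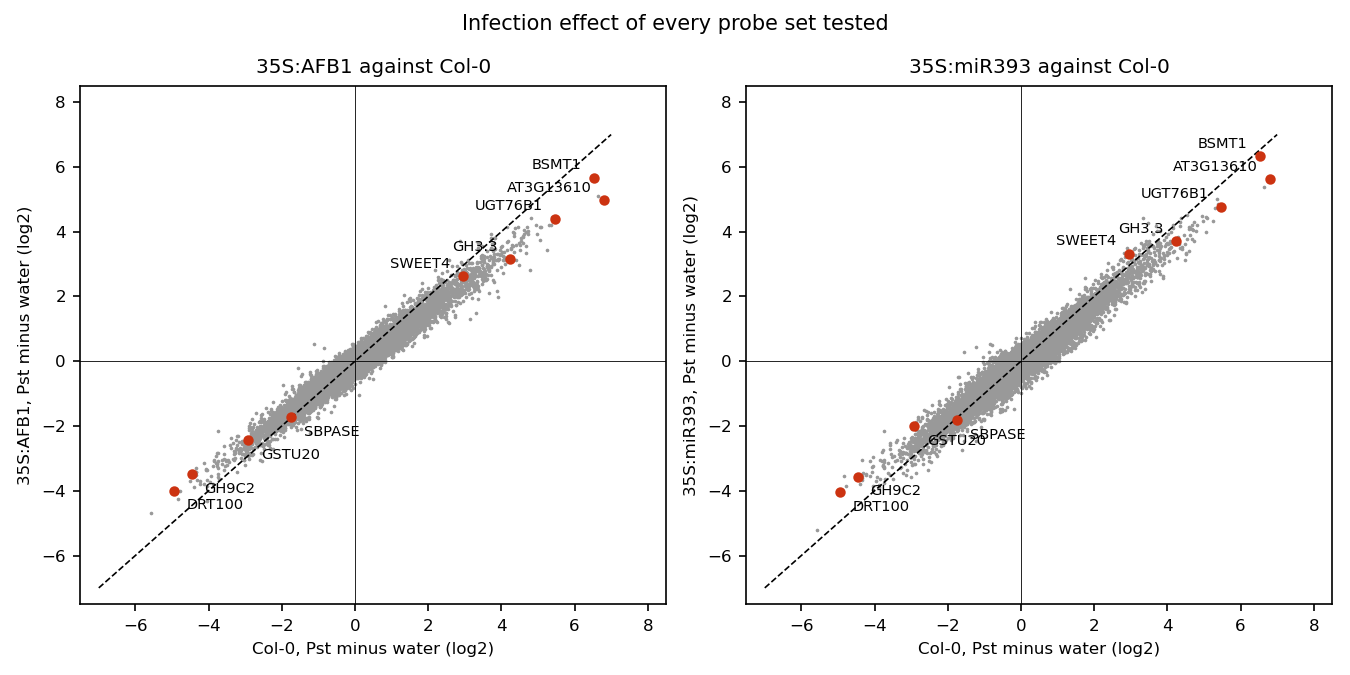
Log2 change on infection (Pst minus water) of every tested probe set in Col-0 (horizontal) against 35S:AFB1 and 35S:miR393 (vertical), with the dashed line of equal change and named genes in red. The points follow a line flatter than that of equal change, with slopes of 0.84 and 0.89 by total least squares.

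The interaction tests ask whether infection acted differently in a transgenic line than in Col-0, and no single gene passed. For 35S:AFB1 the difference of responses was -1.10 for GH3.3 (SE 0.67), -0.85 for BSMT1, -0.52 for EIN3 and 0.40 for IAA29. For 35S:miR393 it was -0.53 for GH3.3, -0.73 for EIN3 (SE 0.22) and 0.50 for IAA29. The calls that differ between lines in the infection comparisons, such as IAA29, are therefore not shown to differ between the lines. limma called 0 probe sets for 35S:AFB1, with 707 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999, and 0 for 35S:miR393, with 973 and 0.996. Of 13 lists 0 passed by camera, by fry or with an estimated correlation, and the smallest camera adjusted p was 0.574 for 35S:AFB1 and 0.459 for 35S:miR393. Without 35S:AFB1 water replicate 3 the count for that line was 1. In simulated data the interaction test found 1.49% of shifts of 0.5, 52.2% of shifts of 1 and 95.5% of shifts of 2, so differences in response below about 1 were mostly not detectable here.

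In water, the comparison of 35S:AFB1 with Col-0 asks what the receptor construct changes in leaves without bacteria, and few genes passed. AT1G50950 was higher by 1.87 on the log2 scale (6.45 ± 0.91 against 4.59 ± 0.17, SD, n = 3, the Col-0 mean lying near background), AT2G39400, which encodes a hydrolase of the alpha/beta fold, by 0.82 (8.56 ± 0.22 against 7.74 ± 0.14), and the oxygenase gene AT3G19010 by 0.78. AT1G29520 was lower (-0.87, SE 0.14). The other 3 calls, singled out after their values were seen, were probe sets that the annotation does not list, 1 higher (0.83) and 1 lower (-1.09), and a probe set that it gives to 2 genes (-1.18, SE 0.17), at 8.91 ± 0.42 against 10.09 ± 0.25 (SD, n = 3).

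limma called 7 probe sets in this comparison of 35S:AFB1 with Col-0 in water, 4 higher and 3 lower, with a smallest adjusted p of 0.0411 and 2236 at an unadjusted p under 0.05. With array median centring the 7 calls were 1 higher and 6 lower, and with quantile normalization 6 calls were 1 higher and 5 lower. Groups did not overlap for 2914 probe sets (12.8%), where chance gives 10%. Without Col-0 replicate 1 the count was 1, without Col-0 replicate 2 or 35S:AFB1 replicate 1 it was 0, and without 35S:AFB1 replicate 3 it was 2. Of 13 lists 0 passed by camera, by fry or with an estimated correlation, and the pattern-triggered immunity list came nearest (median 0.41, camera adjusted p = 0.0587). Adjusted over the list alone, 1 senescence gene was higher and 1 sugar transport gene lower. Among genes of interest that did not pass, the differences were 0.35 for GH3.3, 0.63 for EIN3 (adjusted p = 0.256), 0.98 for WRKY53 and -0.35 for IAA29.

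The comparison of 35S:miR393 with Col-0 in water asks the same of the microRNA construct, and no gene passed. The probe sets called for 35S:AFB1 differed here by 0.47 (AT2G39400, adjusted p = 0.280), 0.67 (AT3G19010, adjusted p = 0.237), 0.40 (AT1G50950), -0.64 (AT1G29520), -0.23 (the probe set given to 2 genes), and 0.73 (adjusted p = 0.237) and -0.71 (adjusted p = 0.265) for the higher and the lower unlisted one. All of them lay on the same side of Col-0 as in 35S:AFB1, and none was called in water between the transgenic lines. Infection of Col-0 moved AT2G39400 (1.31), AT3G19010 (1.94), AT1G29520 (-0.92) and the higher (1.12) and lower (-1.05) unlisted probe sets to that side too. The shared Col-0 water arrays may account for part of these differences, which are not shown to be particular to 35S:AFB1. EIN3 differed by 0.62 (adjusted p = 0.272), WRKY53 by 1.17, GH3.3 by -0.22 and IAA29 by -0.34. limma called 0 probe sets, with 2238 at an unadjusted p under 0.05 and a smallest adjusted p of 0.237. Groups did not overlap for 3416 probe sets (15%), where chance gives 10%. Replicate numbers paired these groups. With the replicate number as a block the count was 0, and as a block within treatment it was 33, WRKY53 among them. Without Col-0 replicate 3 the count was 153. Of 13 lists 0 passed by camera, by fry or with an estimated correlation.

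**Figure D3:**
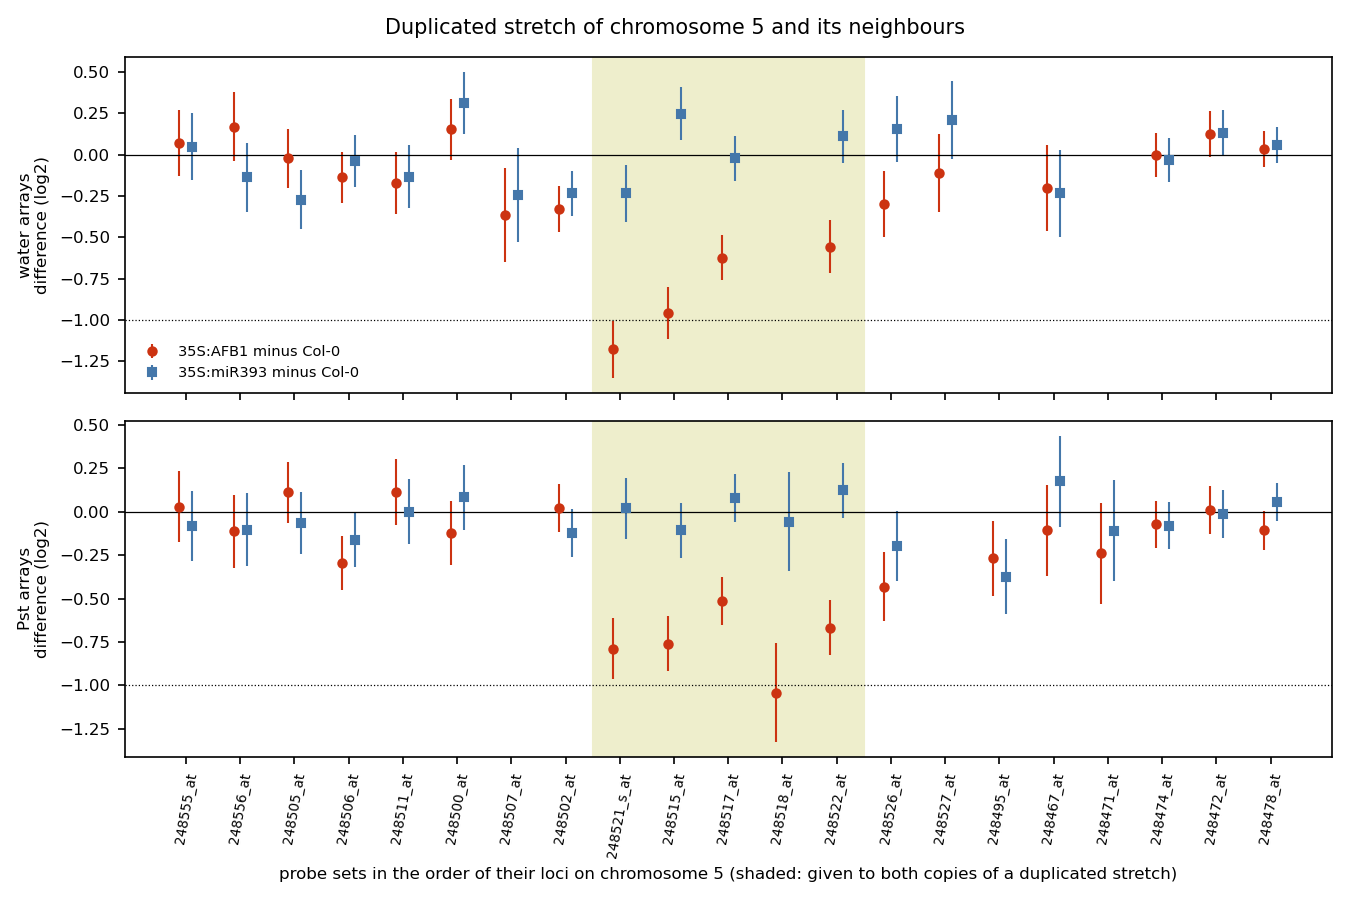
Log2 difference from Col-0 of 35S:AFB1 (red circles) and 35S:miR393 (blue squares), with SE, for probe sets in gene order along a stretch of chromosome 5, in water and in Pst, where Col-0 lies above 6. In the shaded part, probe sets that the annotation gives to both copies of a duplicated block lie between -1.18 and -0.52 in 35S:AFB1, and the dotted line is at -1.

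Among infected leaves, the comparison of 35S:AFB1 with Col-0 asks whether the receptor construct changes the infected state, and a single probe set passed. It is not listed in the annotation, was singled out after its values were seen, and was higher by 2.95 on the log2 scale (SE 0.37, adjusted p = 0.0176), at 8.19 ± 1.02 against 5.24 ± 0.08 (SD, n = 3). The Col-0 mean lay near background, so the size of this difference is not exact. In water it lay at 7.65 against 6.35 (adjusted p = 0.308). GH3.3 differed by -0.75, BCAT4 by 0.85 and SAG101 by 0.30, and none of them passed. Of the gene lists, 3 lay slightly higher than in Col-0 by camera, with 0 members called over all probe sets or adjusted over the list alone. They were photosynthesis (median 0.13, camera adjusted p = 0.000951, adjusted p = 0.282 with an estimated correlation), aliphatic glucosinolate (median 0.44, 0.0490, adjusted p = 0.224 with an estimated correlation) and pattern-triggered immunity (median 0.30, 0.0490, adjusted p = 0.224 with an estimated correlation).

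By fry those 3 lists had adjusted p of 0.472, 0.466 and 0.466 for 35S:AFB1 against Col-0 in Pst. Without Col-0 replicate 2 they had camera adjusted p of 0.932, with the direction turned, 0.608 and 0.172, and without 35S:AFB1 replicate 1 of 0.237, 0.237 and 0.105. Without Col-0 replicate 3 the glucosinolate and immunity lists had 0.0737 and 0.277, and without 35S:AFB1 replicate 3 they had 0.0770 and 0.291, with array median centring both had 0.0555, with the spike-in gap as covariate both had 0.0730, and without the dimmer probe sets they had 0.0507 and 0.205. limma called 1 probe set with 599 at an unadjusted p under 0.05, and groups did not overlap for 1615 (7.10%), where chance gives 10%. Replicate numbers paired these groups, and with the number as a block the count was 3, as it was within treatment. Without any of the Col-0 replicates 1, 2 and 3, or without 35S:AFB1 replicate 1 or 2, the count was 0, and in those fits the difference of this probe set lay between 2.61 and 2.98. In simulated data 83.6% of shifts of 1 and 26.9% of shifts of 0.5 were found at this group size.

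The comparison of 35S:miR393 with Col-0 among infected leaves gave no called gene. GH3.3 differed by -0.75, WRKY53 by 0.70, AT1G22690 by 0.82 and AT2G31790 by 0.57, and none of them passed. By camera the aliphatic glucosinolate (median 0.67, camera adjusted p = 0.0287, adjusted p = 0.526 with an estimated correlation) and photosynthesis lists (median 0.15, camera adjusted p = 0.00855, adjusted p = 0.77 with an estimated correlation) lay higher than in Col-0, with 0 members called, also when adjusted over the list alone. By fry both had an adjusted p of 0.795. Without Col-0 replicate 2 both had 0.905, with the direction of photosynthesis turned, and without 35S:miR393 replicate 1 both had 0.329. Without Col-0 replicate 3 the glucosinolate list had 0.0833, and without 35S:miR393 replicate 2 it had 0.0798. limma called 0 probe sets, with 575 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999, and with the replicate number, which paired these groups, as a block the count was 0. Groups did not overlap for 1792 probe sets (7.88%), where chance gives 10%.

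Compared directly, 35S:miR393 and 35S:AFB1 differed in a single probe set in each treatment, both singled out after their values were seen. In water a probe set of the duplicated block on chromosome 5, which the annotation gives to 2 genes, was higher in 35S:miR393 by 1.21 (SE 0.16, adjusted p = 0.0339), at 7.92 against 6.72. In Pst the unlisted probe set called for 35S:AFB1 against Col-0 was lower in 35S:miR393, with a log2 difference of -2.87 (adjusted p = 0.0249), the 35S:miR393 mean of 5.32 lying near background. GH3.3 differed by -0.57 in water and by 0.01 in Pst, PDF1.2 by -1.43 in water and EFR by -0.34 in Pst, and none of them passed. Adjusted over the list alone, THI2.1, a thionin gene of the jasmonate response list, was higher in Pst by 0.37 (SE 0.10).

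limma called 1 probe set for 35S:miR393 against 35S:AFB1 in water, with 554 at an unadjusted p under 0.05, and 1 in Pst, with 473. Groups did not overlap for 1541 (6.77%) and 1884 (8.28%), where chance gives 10%. The water count was 0 without 35S:AFB1 replicate 1 or without any of the 35S:miR393 replicates 1, 2 and 3. Without 35S:AFB1 replicate 3 it was 1, for another probe set, lower in 35S:miR393, while the one above differed by 1.03 and was not called. The Pst count was 0 without 35S:AFB1 replicate 1 or 2 or any of the 35S:miR393 replicates 1, 2 and 3. Replicate numbers paired the Pst groups, where the count was 1 with the number as a block and 2 with a block within treatment. Of 13 lists 0 passed in either treatment by camera, by fry or with an estimated correlation, and the guard cell markers in Pst came nearest (camera adjusted p = 0.0880).

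The constructs were made to move auxin receptor levels in opposite directions, so their differences from Col-0 were also set side by side. Among probe sets at an unadjusted p under 0.05 in both lines, 988 differed from Col-0 in the same direction in water, 95 in Pst and 296 in the interaction, and 0 in opposite directions in each. By limma 0 probe sets were called in both lines. Both comparisons use the same Col-0 arrays, which alone makes the differences alike. In water the correlation across probe sets was 0.727, where simulated unchanged lines gave 0.501, with a covariance of 0.0435 against 0.0201. In Pst it was 0.612 against 0.501, with a covariance of 0.0185 against 0.0201, and for the interaction 0.750 against 0.501, with 0.0521 against 0.0403. The simulation takes arrays as independent, while replicate numbers paired all lines in Pst and Col-0 with 35S:miR393 in water, which alters what unchanged lines would share. With draws of arrays, which also break that pairing, the water correlation ranged from -0.49 to 0.80. The 3 Col-0 arrays of a treatment cannot be divided into separate controls of at least 2 arrays, so part of the excess may come from the shared arrays and it is not read as an effect common to both lines.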

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

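All tests of the block on chromosome 5 and of the difference between replicates 2 and 1, the test of the shared Col-0 arrays, the scores by pairs, and the families of genes by symbol were chosen only after the result was seen.

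A stretch of chromosome 5 stood out in 35S:AFB1, where the probe sets that the annotation gives to both copies of a duplicated block lay below Col-0, by a median of -0.76 on the log2 scale over 9 values above the floor (-1.18 to -0.52), against 0.02 in 35S:miR393. Scaling or labelling of the arrays is argued against by 16 flanking probe sets, whose median was -0.11. On the mean of both treatments the block had a median of -0.61, and 1 of 7782 runs of as many neighbouring probe sets was as low, which lay at the block itself, while the lowest run outside it was at -0.35. The block was picked because a member of it was called low, and the run includes called members. The count therefore cannot decide on chance clustering. Loss of 1 of the 2 copies in the 35S:AFB1 line may account for it, since it needs a median between -1.5 and -0.5 and the observed value is -0.76. The probe sets of the block that were not called had a median of -0.62 over 5 values (-1.04 to -0.52). This stays a hypothesis found and tested on the same data, and whether such a loss belongs to the construct or to the plants used is open.

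The mean infection response was smaller in both transgenic lines than in Col-0, at scores of 0.89 in 35S:AFB1 and 0.95 in 35S:miR393 against 1.12 in Col-0. The score places each array along the mean infection effect of the other lines, in units of that effect. A larger response in 1 line thus lowers the scores of the others, and the scores can overstate the gap. By the mean size of the log2 changes over all probe sets, 35S:AFB1 reached 0.84 and 35S:miR393 0.88 of Col-0. A single Col-0 array is argued against as the whole cause, since the ratio of the Col-0 response to the larger of the others was 1.17 with all arrays and 1.07 at its lowest, without Col-0 Pst replicate 2. Without that array the excess was smaller, but replicate 2 scored above replicate 1 in Pst leaves of every line. Only the Col-0 array was left out, so the fall of the ratio cannot tell that array from this shared difference. A part of the excess that comes from that array stays open. Labelling quality read from the spike-in controls cannot be told apart from a line effect, because the gap of the Col-0 water arrays (-1.15, SD 0.26, n = 3) differs from the other groups and predicts the water differences only in part (r = 0.28 and 0.38). The Col-0 arrays shared by both comparisons may also account for it, with a covariance of the interactions of 0.0521 inside the range of draws of arrays (up to 0.137), which leave out the pairing by replicate number. An effect of the constructs stays open too. Against Col-0 the mean score of 35S:AFB1 differed by 0.17 in water and -0.06 in Pst, and that of 35S:miR393 by 0.09 and -0.08. Much of the gap thus lies in the water leaves, so it is not shown to be a weaker reaction to bacteria. A response by replicate is the Pst score minus the water score of the same number. Those numbers did not pair water with Pst within a line. In replicate 1 the response of 35S:miR393 (0.86) was above that of Col-0 (0.80), and in replicates 2 and 3 below. In the order given, the score differences did not pass an exact two-sided permutation test (p = 0.2, 0.7, 0.4 and 0.6, each 0.7 after adjustment, where the smallest possible with 3 against 3 arrays is 0.1). That test leaves out the pairing by replicate number. By pairs, 35S:AFB1 scored below Col-0 in 3 of 3 in Pst (mean -0.06, SD 0.06, n = 3, exact sign-flip p = 0.25, the smallest possible), and 35S:miR393 in 2 of 3 in Pst and 1 of 3 in water.

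The response of replicate 2 was larger than that of replicate 1 in each line, while replicate 3 exceeded replicate 1 in Col-0 only, with scores for replicates 1, 2 and 3 of 0.80, 1.34 and 1.22 in Col-0, 0.76, 1.14 and 0.76 in 35S:AFB1, and 0.86, 1.16 and 0.84 in 35S:miR393. Labelling quality read from the spike-in gap is argued against as the whole cause, since in a fit of the scores of all 18 arrays the response of replicate 2 exceeded that of replicate 1 by 0.40 (SE 0.08) without the gap and by 0.41 (SE 0.08) with it. A difference in the strength of infection between replicate sets is argued against for the part of the pattern in water leaves, where replicate 2 minus replicate 1 had a mean of -0.18 over the lines (SD 0.06, n = 3). For the part in Pst leaves (0.23, SD 0.07, n = 3) it cannot be told apart from another difference between replicate sets, because those values are the pattern itself. As above, each response sets a Pst array against an unpaired water array of the same number. No batch is given in the labels, so what the replicates shared is open, and no biological explanation was tested.

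Of the families of genes that share a symbol, some had an infection effect in a transgenic line that differed from that in Col-0 by camera on the interaction, and none of them with an estimated correlation. Camera also called 13 of 30 families for 35S:AFB1 against Col-0 in water and 7 for 35S:miR393, against 2 and 1 in Pst, and 0 of these with an estimated correlation, so these interactions are not shown to arise in the infected leaves. For 35S:AFB1 the median interactions were -0.30 for autophagy genes (ATG, camera adjusted p = 0.0390, adjusted p = 0.525 with an estimated correlation), 0.23 for expansins (EXPA, 0.0325 and 0.136), -0.23 for NET actin-binding proteins (0.0384 and 0.136), 0.0908 for carboxypeptidase-like genes (SCPL, 0.0390 and 0.136), -0.26 for SEC genes (0.0244 and 0.257), 0.14 for SWEET transporters (0.0384 and 0.187), 0.12 for tetraspanins (TET, 0.0390 and 0.136), -0.33 for VPS genes (0.0390 and 0.425) and 0.31 for organelle-encoded genes (0.00796 and 0.684). For 35S:miR393 they were 0.40 for expansins (0.00663 and 0.10), -0.14 for NET (0.0126 and 0.10) and 0.51 for organelle-encoded genes (5.25e-08 and 0.620).

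Among the manufacturer's control probe sets, which no comparison used, 4 for ubiquitin were higher in the 9 Pst arrays than in the 9 water arrays, without overlap. The differences of means were 0.55 for AFFX-Athal-Ubq_3_f_at, 0.63 for AFFX-Athal-Ubq_5_f_at, 0.49 for AFFX-r2-At-Ubq-3_x_at and 0.54 for AFFX-r2-At-Ubq-5_x_at.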

How the results depend on the processing

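The fit with a block within treatment and the spike-in gap as covariate were chosen after seeing the data. Of 117 calls of named genes in the infection comparisons, counted per gene and comparison, 100 held under every alternative fit, over 1632 values 1577 were the same and 55 weaker, and 0 reversed. These fits include leaving out arrays but not the stricter thresholds, an adjusted p under 0.01 and a log2 change of at least 1. Those were counted over all probe sets only. Counted likewise, of 8 not called there 6 stayed so throughout. The 10 calls between lines held least, with 58 of 145 values the same and 87 weaker, and 0 of them held under every alternative. Of 156 results of named genes not called between lines or in an interaction, 155 stayed so. The 18 called lists gave 221 values, of which 155 were the same, 64 weaker and 2 reversed. Signal over background limits the dim probe sets, which include members of the GH3 and immunity lists. Both measured salicylic acid genes were kept when the dimmer probe sets were left out. The weaker result of that list there was thus not a loss of dim members. Except where said, the cause was not tested.

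Requiring a log2 change of at least 1, which by construction leaves fewer, gave 4604 calls for infection in Col-0, 3600 in 35S:AFB1 and 3943 in 35S:miR393. For 35S:AFB1 against Col-0 in water (7 calls) it gave 3, leaving out the dimmer probe sets 0, trend with robust eBayes 0, array weights 4, the spike-in gap 0, only the compared groups 0 and an adjusted p below 0.01 gave 0. With the gap, the loss of calls was not a loss of the differences for the genes given here. AT1G50950 differed by 1.87 (SE 0.30), and by 1.99 (SE 0.36) with the gap, AT3G19010 by 0.78 (SE 0.13), and by 0.76 (SE 0.16) with the gap, and AT2G39400 by 0.82 (SE 0.12), and by 0.68 (SE 0.13) with the gap. With trend and robust eBayes or only the compared groups the difference is that of the same group means and cannot change. Only its SE can, for AT1G50950 to 0.42 with only the compared groups. Leaving out the dimmer probe sets likewise leaves the differences of the kept ones as they are. For 35S:AFB1 against Col-0 in Pst (1 call) leaving out the dimmer probe sets gave 0, trend with robust eBayes 2, only the compared groups 0 and an adjusted p below 0.01 gave 0. For 35S:miR393 against 35S:AFB1 (1 call in each treatment), only the compared groups and an adjusted p below 0.01 gave 0 and 0, the spike-in gap 0 in water, and leaving out the dimmer probe sets 0 in Pst.

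With the replicate number as a block the counts were 10476, 9021 and 9376 for infection in Col-0, 35S:AFB1 and 35S:miR393, 14 for 35S:AFB1 against Col-0 in water and 3 in Pst. With a block within treatment they were 30 for 35S:AFB1 against Col-0 in water and 3 in Pst, 33 for 35S:miR393 against Col-0 in water, and 0 in water and 2 in Pst for 35S:miR393 against 35S:AFB1. The replicate block ended the GH3 list call of infection in Col-0 (adjusted p = 0.0525) and added AT4G34270 in 35S:AFB1 and UGT74B1 in 35S:miR393 among named genes. It changed no other call of a named gene in an infection or of a called list, and the block within treatment added WRKY53 for 35S:miR393 in water.

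Leaving out each array in turn gave counts of 8244 to 9366, 6168 to 7507 and 6917 to 7573 for infection in Col-0, 35S:AFB1 and 35S:miR393. The range was 0 to 8 for 35S:AFB1 against Col-0 in water and 0 to 1 in Pst, 0 to 153 for 35S:miR393 against Col-0 in water (153 without Col-0 replicate 3), 0 to 1 for 35S:miR393 against 35S:AFB1 in each treatment, and 0 to 1 for the interaction of 35S:AFB1 (1 without 35S:AFB1 water replicate 3). The 18 list calls became 0 with an estimated correlation, 30 with fry, which asks another question, 6 without the dimmer probe sets, and 12 (without 35S:miR393 water replicate 1) to 25 (without Col-0 Pst replicate 1). The photosynthesis list against Col-0 in Pst had adjusted p from 7.52e-09 (without Col-0 replicate 1) to 0.932 in 35S:AFB1 and from 7.95e-09 (without Col-0 replicate 1) to 0.905 in 35S:miR393, and its direction reversed without Col-0 Pst replicate 2 (0.932 and 0.905). The overlap of infection calls between lines (6726 in all 3) was not recounted without single arrays. It ran from 5703 to 7574 over array median centring, leaving out the dimmer probe sets and the replicate block.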

Other observations

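The families of genes by symbol below were chosen after the data were seen, and so were the genes named from them, while the splits of the arrays were planned, except for counting at an unadjusted p. Infection raised most measured autophagy genes in Col-0. Of 8 measured ATG genes 7 rose, with a median change of 1.24 (camera adjusted p = 0.00533, adjusted p = 0.317 with an estimated correlation), led by the autophagosome protein genes ATG8H (2.89), ATG8E (2.03) and ATG8B (1.70). In 35S:AFB1 5 of 8 rose (median 0.88) and in 35S:miR393 7 of 8. Of 10 VPS genes, which act in sorting at endosomes, 6 rose and 2 fell in Col-0 (median 0.91, camera adjusted p = 0.0328, adjusted p = 0.357 with an estimated correlation), from VPS60.1 (2.62) to VPS9B (-1.29). Of 9 SEC genes 5 rose (median 0.57, camera adjusted p = 0.0142, adjusted p = 0.317 with an estimated correlation), among them the exocyst genes SEC15B (1.68) and SEC6 (1.26). Of 12 ubiquitin-specific protease genes (UBP) 6 rose (median 0.43, camera adjusted p = 0.0283, adjusted p = 0.484 with an estimated correlation), and of 9 PUB ubiquitin ligase genes 4 rose, led by PUB23 (2.68) and PUB24 (2.24).

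Of 10 expansin genes, whose products loosen the cell wall, 5 fell and 0 rose on infection of Col-0 (median -0.38, camera adjusted p = 0.0283, adjusted p = 0.278 with an estimated correlation), led by EXPA8, with -4.07 in Col-0, -3.36 in 35S:AFB1 and -3.43 in 35S:miR393, and EXPA4 (-2.44 in Col-0). Among single genes of other families, XTH32, which encodes a xyloglucan transferase, fell by 3.56 on the log2 scale in Col-0, and the peptide genes RALFL24 (-3.14) and RALFL34 (-2.99) fell too. Glycosyltransferase genes moved both ways, with 15 of 47 UGT genes higher and 11 lower in Col-0, among them UGT76D1 (2.76), UGT76E12 (3.53) and UGT88A1 (-1.77). Of 20 beta-glucosidase genes 6 rose and 3 fell, BGLU46 (3.23) and BGLU31 (2.78) among the risen and BGLU40 (-2.10) among the fallen. Over all 22746 probe sets 4794 were higher and 4796 lower in Col-0 (42.2% called). The UGT and beta-glucosidase counts are not read as family responses apart from that share.

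Other splits of the same 6 arrays were refitted for each comparison of 2 groups, and 10 splits are too few for a share under 0.05. The infection counts were 9590 in Col-0, 7950 in 35S:AFB1 and 8390 in 35S:miR393, each reached by 1 of 10 splits, the real one, with 46, 1 and 0 in the highest other. For 35S:AFB1 against Col-0 in water 3 of 10 splits gave at least the 7 real calls, and the highest other gave 696, with Col-0 replicate 1 and 35S:AFB1 replicates 1 and 3 on one side, which points to a structure of the samples. In Pst 2 of 10 splits gave at least the 1 real call, and the highest other gave 286, with the same replicate numbers on one side, which again points to a structure of the samples. For 35S:miR393 against Col-0, where limma called 0, 2 of 10 splits gave at least the real 2238 probe sets at an unadjusted p under 0.05 in water, with 2299 in the highest other. In Pst 8 of 10 gave at least the real 575, and the 2466 of the highest other point to a structure of the samples. For 35S:miR393 against 35S:AFB1 the real count of 1 was reached by 1 of 10 splits in each treatment, and the highest other was 0. At an unadjusted p under 0.05, however, 7 of 10 splits gave at least the real 554 in water, with 2087 in the highest other. In Pst 7 of 10 gave at least the real 473, with 1572 in the highest other. Where replicate numbers pair the arrays, the real split parts all 3 pairs and so do 3 others, of which the highest gave 0 calls for 35S:miR393 against Col-0 in water, and 0 for each comparison in Pst. At an unadjusted p under 0.05 these 3 gave up to 736 in water, against the real 2238. In Pst they gave up to 329 for 35S:AFB1 against Col-0 (real 599), 687 for 35S:miR393 against Col-0 (real 575) and 536 for 35S:miR393 against 35S:AFB1 (real 473). The 6 splits that part 1 pair gave up to 1 call for 35S:miR393 against Col-0 in water, where they hold the 2299, and up to 286 for 35S:AFB1 against Col-0 in Pst. Splits within pairs are again too few for a share under 0.05. For the interactions, with 0 called, 84 of 100 splits gave at least the real 707 probe sets at an unadjusted p under 0.05 for 35S:AFB1 and 49 of 100 at least the real 973 for 35S:miR393, so chance is not excluded. The highest others gave 4094 and 3919, and 627 and 16 calls, which points to a structure of the samples. The splits of the interactions were drawn by line within each treatment and leave out the pairing by replicate number, which can raise the counts of the others.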
